A study of Homo sapiens with 4 samples.

How the data were processed

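Gene expression was measured on 4 single-colour Illumina bead arrays, each hybridised with biotin-labelled target made from total RNA of U87 cells, an established human glioblastoma line. Cells had been transfected with non-targeting siRNA (2 arrays) or with BCL6 siRNA (2 arrays). The labels call the arrays duplicates and do not say whether they came from separate transfections. The p-values of single genes therefore measure the spread between these arrays, which may be technical. Those of gene lists by camera with a preset correlation or by Fisher's test, described below, compare genes with other genes. They do not measure that spread directly. The labels give no slide, scan or hybridisation batch. The siRNA sequences and the time after transfection are not given in the sources used here.

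The authors deposited a table of non-normalized intensity values, on a linear scale, for 47323 probes. BeadStudio is the one tool named, per the submitters' processing notes, without its version or settings. No signal was below 16, and the arrays' intensity quantiles differed, so the values had been neither background-subtracted nor normalized between arrays. Beside each intensity the authors deposited a fraction headed as a detection p-value. That fraction never fell as its own array's signal rose and was 1 for the brightest probes, so it is 1 minus the detection p-value, and it was converted before use. Read literally as a p-value, it would have kept 737 probes with a median signal of 38.2, none of which passed the filter used here. The authors also deposited log2 values for the same arrays. These equal the quantile-normalized log2 of the non-normalized signal, with no background correction, to within 5.0e-09, so their scale is known and they are not centred (median 5.74 in each column). Both tables were joined by probe identifier because their rows are in different orders.

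Of the 47323 probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 were unnamed here. Of the probes with 1 symbol, 30074 had an Entrez identifier in the reference gene table (RefSeq, GRCh38.p14), which changed no symbol. That table served for names alone, and no coordinates are given because no source names the build behind the probe design. Some members of the gene lists have no named probe and were not analysed here. The signals were background-corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3 (normexp with an offset of 16, the negative-control distribution inferred from the detection p-values, then quantile normalization and log2). A probe was tested if its detection p was under 0.05 on at least 2 of the 4 arrays, which left 20130 probes. Where a gene had several tested probes, the one with the highest mean over all 4 arrays stood for it, a choice blind to the groups. This gave 16128 features, of which 11515 were named genes and 4613 were single unnamed probes. Unnamed probes stay in the counts and are not listed one by one.

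Groups were compared with limma (lmFit and eBayes without trend, two-sided), with the 4 arrays in 1 model, no replicate block, and Benjamini-Hochberg adjustment over the 16128 features. The threshold was an adjusted p under 0.05. The residual degrees of freedom were 2 and the prior ones 4.41. Fold changes are BCL6 siRNA over non-targeting siRNA, on the scale of the normalized log2 values, whose offset shrinks the change of dim genes. A probe above background on neither array of a group has only a bound there, and its fold was set against the lowest signal detected on each array. On data simulated from these arrays' means and spread (20 runs, 16128 features, 200 changed), 39.5% of 2-fold falls, 40.1% of 2-fold rises, 96.0% of 4-fold falls and 96.9% of 4-fold rises were recovered, and 4.95% of calls were false. The simulation drew independent genes from the fitted model itself, so a false share near the threshold was built in. It does not measure the share of false calls among the real ones. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.16.

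Before the data were examined, 23 gene lists were fixed, and each was tested with camera (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 23 lists), with camera using an estimated correlation, with fry, and with a two-sided Fisher's exact test of calls against all tested features. A simulated ERK list with all members shifted by -0.5 was found in 100% of runs with the preset correlation. With the estimated one it was found in 0%, so missing that test below does not show that a list did not move. Of unshifted lists, 0.26% were called with the preset correlation. The simulated genes varied independently of each other. That rate therefore does not bear on lists whose members vary together, such as the hypoxia and glycolysis genes (estimated correlation 0.362). The lists held p53 targets, genes that BCL6 represses in B cells, replication, mitosis, ERK output, ErbB and other receptor tyrosine kinases, interferon response, inflammation, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, matrix, neural and glial lineage, Notch, apoptosis, BCL6 corepressors, markers of epithelial, blood and endothelial cells, ribosomal proteins, respiratory chain and reference genes.

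The genes named in the text follow a rule fixed at the same time, except that its largest rises and falls were limited to features with a gene symbol after the data were seen. They are BCL6, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and that were detected on both arrays of a group, up to 4 members per list past the threshold (or, where none passed, the 2 with the smallest p), and 8 genes of prior interest, of which 7 were measured. Other members named beside a list were chosen after their values were seen. The alternatives were no background correction, an offset of 50, median centring, the authors' log2 values, no filter and a stricter filter on dim probes (detection p under 0.01 on 4 arrays), the mean of a gene's probes, a mean-variance trend, a replicate block, leaving out each array, and an adjusted p under 0.1 or a 2-fold minimum. A test over named genes alone was added after the data were seen.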

Results

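Transcript levels were compared between U87 cells given BCL6 siRNA and U87 cells given a non-targeting control siRNA, with 2 arrays per group. U87 is an established human glioblastoma cell line, and BCL6 is a transcriptional repressor of the BTB zinc finger family, best known from germinal-centre B cells. The comparison asks which transcripts change when BCL6 is depleted in glioblastoma cells. Between 41.3% and 42.7% of the 47323 probes were detected on each array, and the median raw signal lay between 51.5 and 56.2. Across features, the normalized values of arrays of the same group correlated at 0.992 and 0.993, and those of arrays of different groups at 0.983 to 0.987; genes are not independent replicates, so these describe the arrays only.

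BCL6 itself, measured by 1 probe (ILMN_1737314), was 2.05-fold lower after BCL6 siRNA. Its raw signal was 712.7 and 659.4 on the control arrays and 372.5 and 303.6 on the knockdown arrays. The normalized log2 level was 9.32 ± 0.07 (SD, n = 2) in the controls and 8.28 ± 0.23 (SD, n = 2) after knockdown, a log2 fold change of -1.03 (SE 0.16, limma adjusted p = 0.0385). The call ended without non-targeting replicate 1 (adjusted p = 0.153), non-targeting replicate 2 (0.133) or BCL6 siRNA replicate 2 (0.136), and with no filter on dim probes (0.0852). The log2 fold change stayed negative in each of these.

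**Figure D1:**
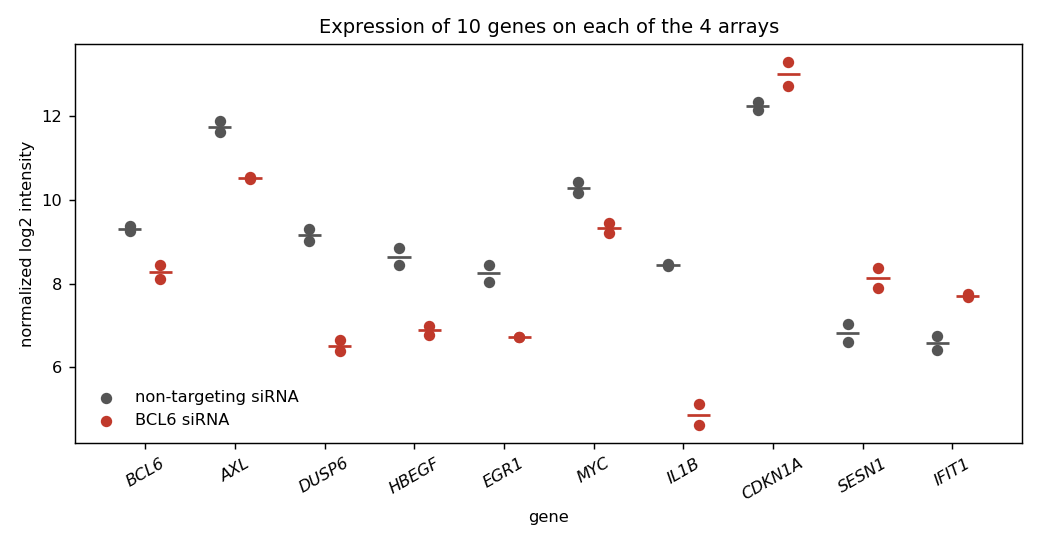
Normalized log2 intensity (vertical axis) of 10 genes (horizontal axis) on each of the 4 arrays; each point is 1 array and each bar the mean of the 2 arrays of a group. The 2 BCL6 siRNA arrays lie below both control arrays for BCL6, AXL, DUSP6, HBEGF, EGR1, MYC and IL1B, and above both for CDKN1A, SESN1 and IFIT1; of these 10 genes CDKN1A did not pass the threshold.

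After BCL6 siRNA, 275 features were lower and 81 were higher, 356 in all. Of these, 225 of the lower and 73 of the higher were named genes. The largest fall of a named gene was that of IL1B, the inflammatory cytokine interleukin-1 beta, which was 11.9-fold lower after background correction (log2 fold change -3.57, SE 0.19, adjusted p = 0.00582). It was detected on 1 of the 2 knockdown arrays, with raw signals of 402.1 and 376.6 in the controls and 63.8 and 56.8 after knockdown, so the size of its fall is uncertain. TMEM167A had a log2 fold change of -3.00. TAGLN3 was 6.52-fold lower and DUSP6, a phosphatase that inactivates ERK and is itself induced by it, 6.25-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 6.76-fold lower by its brightest probe, but a dimmer tested probe of the same gene gave a log2 fold change of 0.081 and the mean of the 2 did not pass (adjusted p = 0.0551). MMGT1 was 5.99-fold lower, with -2.52 and -0.04 on the log2 scale for its dimmer probes. CERK, which phosphorylates ceramide, was 5.72-fold lower and ARPP19, an inhibitor of phosphatase PP2A in mitosis, 5.25-fold. ACLY, the enzyme that makes cytosolic acetyl-CoA from citrate, fell 5.07-fold. STYX was 4.74-fold lower, HSPA5, the main chaperone of the endoplasmic reticulum, 4.71-fold, and ATP6V1C1, a subunit of the vacuolar proton pump, 4.54-fold. For CERK and STYX a second, dimmer probe changed less (log2 fold changes of -0.18 and -0.33), whereas second probes of ACLY (-1.86) and ARPP19 (-2.11) also fell. A second probe gave -1.34 for TMEM167A, and -1.27 for ATP6V1C1 against -2.18 by its brightest, a value that did not pass (adjusted p = 0.0638 over all tested probes). Second probes of DUSP6 and TAGLN3 were not above background after knockdown, and so at least 3.08-fold and 1.74-fold lower. That of DUSP6 passed (limma adjusted p = 0.0299 over all tested probes) and that of TAGLN3 did not (0.146). Without background correction the log2 fold changes of IL1B, ANGPTL4 and TAGLN3 were -2.67, -2.14 and -1.99.

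The largest rises were smaller than the largest falls. NFE2, a bZIP transcription factor, was 3.67-fold higher (log2 fold change 1.87, SE 0.13, adjusted p = 0.00818), TELO2 3.50-fold, and KCNJ2, an inward-rectifier potassium channel, 3.25-fold. CH25H, which makes 25-hydroxycholesterol, rose 3.17-fold, and MYLIP, the ubiquitin ligase that directs the LDL receptor to degradation, 2.95-fold. MCF2L rose 2.96-fold, ST3GAL5, the synthase of ganglioside GM3, 2.81-fold, and the chemokine receptor ACKR3, detected on 1 of the 2 control arrays, 2.63-fold. TM7SF2, a sterol reductase, was 2.60-fold higher, VWCE 2.55-fold, and PPARGC1A, a coactivator of mitochondrial gene expression, 2.55-fold (log2 fold change 1.35, SE 0.19). LRRN4CL was not above background on either control array and was at least 2.37-fold higher after knockdown on the background-corrected scale (adjusted p = 0.0149), so the size of its rise is uncertain. Without background correction the log2 fold changes of NFE2 and LRRN4CL were 1.27 and 0.90. With an offset of 50 those of LRRN4CL and ACKR3 were 0.79 and 0.77.

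These counts rested on all 4 arrays, and where 1 array of a group was left out, the other was assumed to vary like the other group. Without non-targeting replicate 1 there were 11 calls, without non-targeting replicate 2 there were 9, without BCL6 siRNA replicate 1 there were 184 and without BCL6 siRNA replicate 2 there were 100; IL1B, TMEM167A, TAGLN3, DUSP6, CERK, ARPP19 and ACLY passed in each of these fits, and the other 42 of the 49 genes that the naming rule took from those past the threshold did not. With no filter on dim probes 26 of the 49 did not pass: BCL6, ANGPTL4, CH25H, ACKR3, VWCE, PPARGC1A, SESN1 (adjusted p = 0.119), TRIAP1, TRIM22, GADD45A, CD44, MYC (0.0977), CDKN1B, EGR1, SPRY4, CBL, AXL (0.0511), IFIT1, IFIT2, CCL20, CA12, ENO2, CCN1, COL5A2, RBPJ and CYCS. Falls made up 77.2% of the calls, against 66.7% (553 lower, 276 higher) in the authors' values without background correction. Over the 3120 features at an unadjusted p under 0.05, the split was nearly even, with 1582 lower and 1538 higher.

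**Figure D2:**
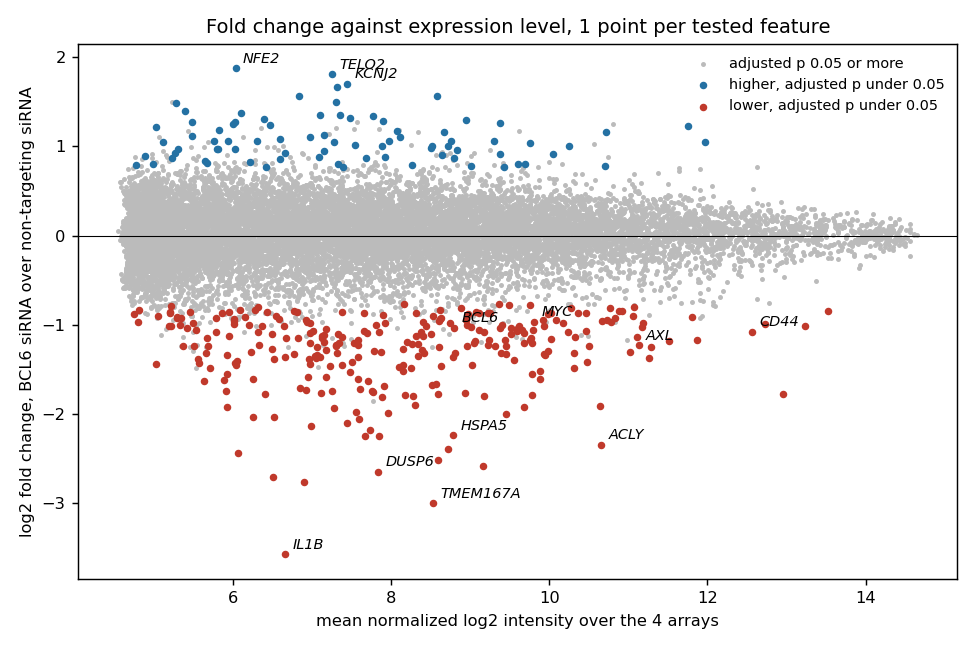
Log2 fold change of BCL6 siRNA over non-targeting siRNA (vertical axis) against the mean normalized log2 intensity of the 4 arrays (horizontal axis), 1 point per tested feature. The 275 features called lower (red) reach -3.57 and the 81 called higher (blue) reach 1.87.

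The ERK pathway output genes, whose transcription follows ERK activity, were lower as a group. Of 22 measured members, 8 fell, none rose and 14 did not pass, while adjusted over the list alone 11 fell. The fallen members were DUSP6, the EGFR ligand HBEGF (3.37-fold), the immediate-early transcription factor EGR1 (2.89-fold), the receptor pathway inhibitor SPRY4 (2.66-fold), the urokinase receptor PLAUR (2.51-fold), the phosphatase DUSP1 (2.02-fold), MYC (1.95-fold) and IER3 (1.80-fold). A second probe of SPRY4, not above background after knockdown, was at least 1.07-fold lower and did not pass, and 1 of the 2 dimmer probes of PLAUR did not pass (-0.78). The median log2 fold change of the list was -0.51 (camera adjusted p = 9.0e-10, and 0.561 with an estimated correlation). Its falls exceeded the 0.375 expected among all tested features (Fisher's exact test, odds ratio 33.9, adjusted p = 7.7e-08). Fisher's test treats genes as independent, so its p does not measure the spread between arrays. Camera with the preset correlation of 0.01 treats them as nearly independent, so its small p does not measure that spread directly either. The background of Fisher's test also holds the 4613 unnamed probes, which no list can contain and which were called less often. The expected count is therefore somewhat low. CCND1, also on this list, had a log2 fold change of 0.08 (SE 0.14, adjusted p = 0.808), which became -0.010 after median centring.

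Among the ErbB receptors and ligands, 2 of 12 measured members fell, none rose and 10 did not pass (2 lower and 1 higher adjusted over the list alone). Those 2 were HBEGF and CBL, a ubiquitin ligase for activated receptors, which was 2.21-fold lower (log2 fold change of its second probe -0.60, which did not pass). EGFR had a log2 fold change of 0.22 (SE 0.18, adjusted p = 0.557), and 0.48 by its second probe. The list as a whole did not pass (median -0.27, camera adjusted p = 0.0914; 0.66 with an estimated correlation), but it did without BCL6 siRNA replicate 2 (adjusted p = 0.0387). Leaving out another array gave adjusted p between 0.122 and 0.234. Of 22 measured genes of other receptor tyrosine kinases and ligands, 2 fell and none rose (2 lower and 2 higher adjusted over the list alone). The receptor AXL was 2.34-fold lower, from a log2 level of 11.8 ± 0.20 (SD, n = 2) to 10.5 ± 0.03 (SD, n = 2), with an adjusted p of 0.0204. Its second probe had a log2 fold change of -0.97. FGF2, fibroblast growth factor 2, was 2.55-fold lower, while its second probe, not above background after knockdown, did not pass (at least 1.27-fold lower). The median of this list was 0.04, its mean -0.08 and its camera adjusted p 0.665. The AXL call ended when any single array was left out, with adjusted p between 0.0594 and 0.108.

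The p53 target genes were higher as a group. Of 38 measured members, 3 rose, 1 fell and 34 did not pass, and adjusted over the list alone 11 rose and 3 fell. SESN1, a stress-induced inhibitor of mTORC1, rose 2.49-fold, TRIM22 rose 1.97-fold and the growth-arrest gene GADD45A 1.75-fold, while TRIAP1, an inhibitor of apoptosis, fell 2.30-fold. The median log2 fold change was 0.24 (camera adjusted p = 0.00876, and 0.66 with an estimated correlation). The 3 rises exceeded the 0.191 expected (Fisher's exact test, odds ratio 17.6, adjusted p = 0.0209), with the limits of that test given for the ERK list. The GADD45A call ended after median centring (adjusted p = 0.0569) and with the mean of its probes (0.057). CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 0.76 (SE 0.22, adjusted p = 0.135), with both knockdown arrays above both control arrays, and passed in the authors' values (adjusted p = 0.0433). MDM2 had one of 0.35 (SE 0.22, adjusted p = 0.462).

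Of 18 measured genes that BCL6 represses in B cells, 2 rose and 2 fell (5 and 3 adjusted over the list alone). GADD45A and the cell cycle inhibitor CDKN1B (1.73-fold) rose, while MYC and the hyaluronan receptor CD44 (2.11-fold) fell. The calls of both rises ended after median centring (adjusted p = 0.0569 for GADD45A and 0.0619 for CDKN1B) and with the mean of a gene's probes (0.057 and 0.0751). The list had a median of 0.09 and a camera adjusted p of 0.555. PRDM1, a classic BCL6 target in B cells, had a log2 fold change of 0.35 (SE 0.16, adjusted p = 0.296).

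Of the proliferation lists, neither passed as a group in the fit of all 4 arrays. Of 35 mitosis genes, 1 fell and none rose, as adjusted over the list alone: BIRC5, the apoptosis inhibitor survivin, was 2.35-fold lower, and the list's median was 0.09 (camera adjusted p = 0.358). Of 32 replication genes, 1 fell and none rose (2 fell adjusted over the list alone). FEN1, the flap endonuclease of lagging-strand synthesis, was 2.19-fold lower, and the list had a median of -0.06 (camera adjusted p = 0.0934; 0.679 with an estimated correlation). Its result depended on the settings. It passed after median centring (mean -0.20, adjusted p = 0.0382), with no filter on dim probes (0.0475) and without BCL6 siRNA replicate 2 (mean -0.23, adjusted p = 0.00234), whereas without BCL6 siRNA replicate 1 the mean was -0.017 (adjusted p = 0.857). Among 25 apoptosis genes, CYCS, cytochrome c, was 3.06-fold lower and 24 did not pass (1 fell adjusted over the list alone). That list had a median of 0.00 and a mean of -0.08 (camera adjusted p = 0.418).

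The interferon-stimulated genes were higher as a group, with a median log2 fold change of 0.29 (camera adjusted p = 0.00133; adjusted p = 0.561 with an estimated correlation). Of 36 measured members, the antiviral effectors IFIT1 (2.19-fold) and IFIT2 (2.14-fold) rose, none fell and 34 did not pass. Adjusted over the list alone, 3 rose and 2 fell. Of 24 NF-kB and inflammatory genes, IL1B and the chemokine CCL20 (1.89-fold) fell and none rose, against 6 lower and 2 higher adjusted over the list alone. The list had a median of -0.16 and did not pass (camera adjusted p = 0.0844; 0.672 with an estimated correlation). It passed in the authors' values (adjusted p = 0.0458), with an offset of 50 (0.0447), without BCL6 siRNA replicate 1 (0.016) and without non-targeting replicate 2 (0.00253), but not without BCL6 siRNA replicate 2 (0.0826) or non-targeting replicate 1 (0.457; mean -0.25 against -0.37 with all arrays).

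The hypoxia and glycolysis genes were lower as a group. Of 30 measured members, 3 fell, none rose and 27 did not pass, and adjusted over the list alone 9 fell. Besides ANGPTL4, the carbonic anhydrase CA12 was 2.48-fold lower and the glycolytic enzyme ENO2 2.10-fold. The median log2 fold change was -0.27 and 5 members had a positive value (camera adjusted p = 3.5e-05, and 0.66 with an estimated correlation). Enzymes of the glycolytic chain other than ENO2 changed less and none passed. Their log2 fold changes ran from -0.33 for PGK1 to 0.20 for HK2, with -0.13 for LDHA and 0.05 for PKM. The fall of the group therefore lay mainly in other members, among them NDRG1 (-1.17) and SLC2A1 (-0.85), which did not pass singly. Of 32 matrix and mesenchymal genes, the matricellular gene CCN1 (2.28-fold) and CD44 fell and the fibrillar collagen COL5A2 rose 2.09-fold. Adjusted over the list alone, 3 fell and 1 rose (median -0.15, camera adjusted p = 0.0626; 0.66 with an estimated correlation). The matrix list passed in several alternatives, among them the authors' values (adjusted p = 0.0392), the mean of a gene's probes (0.0216), and without BCL6 siRNA replicate 1 (0.0332) or non-targeting replicate 2 (0.00276). It did not pass without BCL6 siRNA replicate 2 (0.112) or non-targeting replicate 1 (0.562), where its mean was -0.09 against -0.17 with all arrays. Of 27 genes of the unfolded protein and integrated stress response, HSPA5 fell and 26 did not pass (2 fell adjusted over the list alone), with a median of 0.03, a mean of -0.12 and a camera adjusted p of 0.429. Of 19 cholesterol synthesis genes none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.416). SQLE and IDI1, which had the smallest p of that list, had log2 fold changes of -0.71 (adjusted p = 0.172) and -0.72 (adjusted p = 0.171).

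In the Notch list, RBPJ, the DNA-binding factor of Notch signalling, was 2.36-fold lower by its brightest probe (at least 1.06-fold by a second, which was not above background after knockdown and did not pass) and the other 11 measured members did not pass, also adjusted over the list alone (camera adjusted p = 0.494). None of 12 neural and glial genes passed, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.39), with log2 fold changes of -0.76 for OLIG2 (adjusted p = 0.0501) and 0.92 for SLC1A3 (adjusted p = 0.0624; 0.00953 in the authors' values). None of 22 BCL6 corepressor and BTB zinc finger genes passed by its brightest probe, and adjusted over the list alone 2 were higher (camera adjusted p = 0.242), with values of 1.27 for ZBTB20 (adjusted p = 0.0641) and 0.63 for ZBTB5 (adjusted p = 0.0949). A second, dimmer probe of ZBTB20 passed (0.97, adjusted p = 0.0341 over all tested probes), as did the brightest in the authors' values (adjusted p = 0.00855).

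Of markers of cell types that the culture should lack, 3 of 12 epithelial, 8 of 16 blood and 1 of 10 endothelial ones were measured. None passed over all genes by its brightest probe, and 1 in each list was lower adjusted over the list alone. Of the epithelial markers, EPCAM had a log2 fold change of -0.70 (-0.07 by its second probe), while KRT18 was not above background after knockdown and so at least 1.03-fold lower. Log2 fold changes of the blood markers were -0.78 for CD68 and -0.43 for LCP1, and that of the endothelial marker TEK was -0.40 (-0.70 by its second probe). CD68 was bright, with raw signals of 5711.3 and 5821.8 on the control arrays. Whether U87 or other cells made its transcript was not tested, so its fall is not evidence of blood cells. Of 2 dimmer probes of CD68, 1 passed (-1.08, adjusted p = 0.0333 over all tested probes) and 1 did not (-1.27), and its brightest passed in the authors' values (adjusted p = 0.0138). The camera adjusted p of the 3 lists were 0.0934, 0.358 and 0.242. The 33 ribosomal protein genes (median 0.03, adjusted p = 0.901) and 30 respiratory chain genes (median -0.01, adjusted p = 0.665) held no call, over all genes or adjusted over the list alone, with values of -0.44 for RPL37, whose second probe had the opposite sign, 0.28 for RPL7, -0.63 for NDUFS1 and -0.38 for NDUFA8. Of 13 reference genes none passed, and 1 was lower adjusted over the list alone (adjusted p = 0.416), although TFRC had a log2 fold change of -0.73 (adjusted p = 0.0595; 0.00876 in the authors' values) and YWHAZ one of -0.49 (adjusted p = 0.161; -0.25 by its second probe).

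Of the 4 lists past the threshold, none passed with an estimated correlation. On simulated data that test found a shifted ERK list in 0% of runs, so missing it does not decide whether these lists moved. By fry, which tests whether a list moves one way and not whether it differs from other genes, the adjusted p was 0.0687 for the ERK output and the interferon-stimulated genes, 0.102 for the p53 targets and 0.227 for the hypoxia and glycolysis genes.

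**Figure D3:**
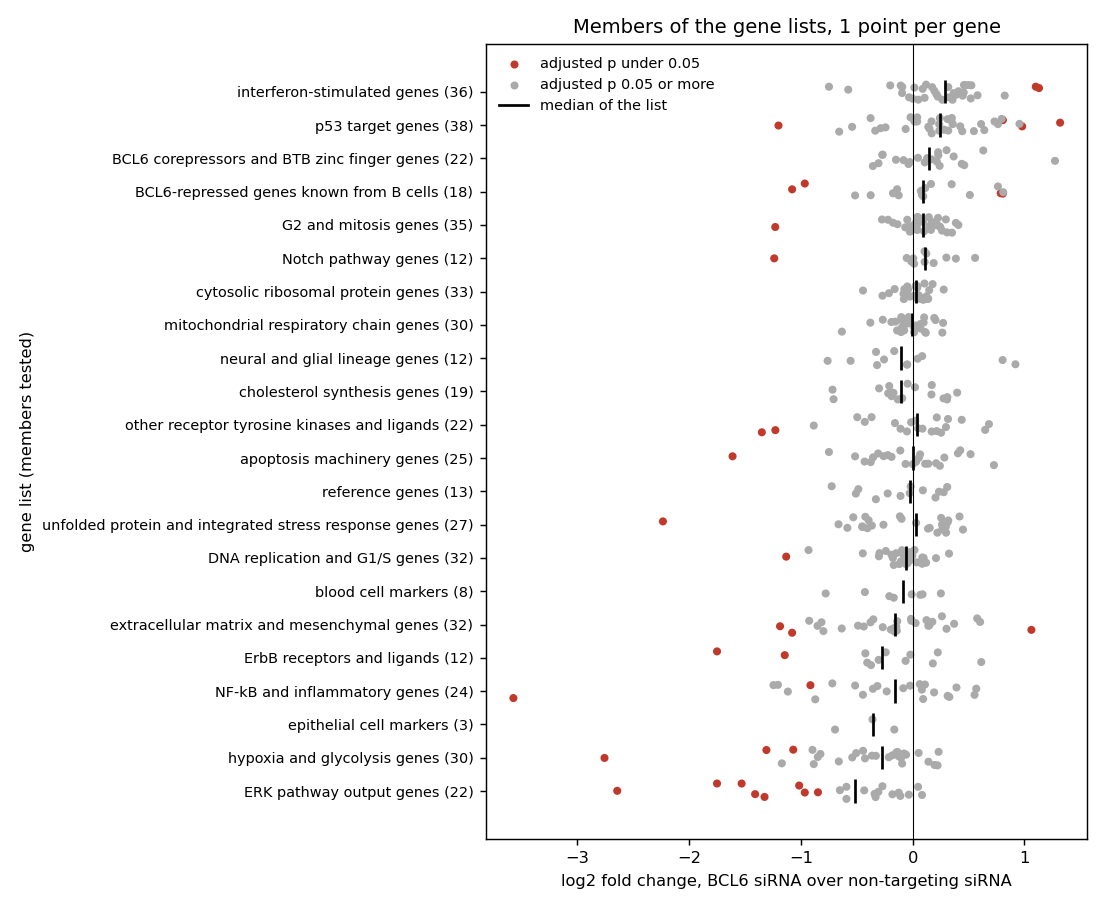
Log2 fold change (horizontal axis) of each tested member of the 22 gene lists with at least 3 members tested (vertical axis, members tested in brackets, ordered by mean); red points have an adjusted p under 0.05 and the black bar is the list's median. The ERK pathway output genes have a median of -0.51 and the interferon-stimulated genes one of 0.29.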

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

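The test over named genes alone was added after the data were seen; the other alternatives were fixed before. BCL6 kept its direction, and the 4 called lists theirs, in each alternative. The count of calls (356; 81 higher, 275 lower) did not: it was 829 (276, 553) without background correction and in the authors' values, which are identical, 1009 (364, 645) with an offset of 50, 998 (349, 649) with a mean-variance trend, 763 (270, 493) with the stricter filter, 110 (13, 97) with no filter, and 826 (275, 551) at an adjusted p under 0.1. With no filter more features were adjusted for; the causes were otherwise not tested. Of the 356 calls, 353 were shared with the fit without background correction, 352 with the trend and 350 with the offset of 50. Falls made up 83.0% of calls after median centring. At least 2-fold rises numbered 47, and among named genes alone 141 were higher. Leaving out 1 array gave 9 to 184 calls (0 to 30 higher, 9 to 154 lower) and a log2 fold change of BCL6 between -1.20 and -0.87; with no filter it was -1.03 but did not pass. Of the 49 genes past the threshold that the naming rule took, 7 passed without each array in turn, 23 with no filter, 43 of the 44 measured with the stricter filter, 46 with the mean of a gene's probes (not ANGPTL4, GADD45A and CDKN1B), 47 after median centring (not GADD45A and CDKN1B) and 49 without background correction. Of 22 named genes that missed the threshold, 10 passed in another setting with the same direction: SQLE, OLIG2, SLC1A3, ZBTB20, ZBTB5, CD68, NDUFA8, TFRC, YWHAZ and CDKN1A.

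The called lists numbered 4 and became 7 with the replicate block (ErbB, inflammatory and matrix genes added) and 0 with an estimated correlation. The matrix list also passed with an offset of 50 (adjusted p = 0.0447), median centring (0.0497) and a trend (0.0321). List overlaps past the threshold numbered 2, and 6 in the authors' values. The replicate numbers are not stated to pair the arrays. Deviations of same-numbered arrays correlated at 0.24, and the replicate block gave 682 calls (205, 477), including all 356. Grouping the arrays by replicate number instead gave 0 calls, with 604 features at an unadjusted p under 0.05. The crossed grouping gave 0 calls, with 216, against 3120 for the real groups. Both regroupings leave the difference between the siRNA groups in the residual spread, so their 0 calls do not exclude a replicate effect. Single genes changed sign where another probe was used or the value was near 0: ANGPTL4 was 0.081 with the stricter filter, RPL37 0.074 with the mean of a gene's probes and CCND1 -0.010 after median centring. Signal over background limits IL1B, TAGLN3, LRRN4CL, ACKR3 and CCL20, which the stricter filter removed.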

Other observations

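The lists in this part, and the tests of what share of the calls fell and of the ERK list without DUSP6, were chosen after the results above had been seen. Adjusted p of these added lists are over the added lists alone, some of them nested, and not over the 23 fixed lists. They are therefore not comparable with those of the fixed lists. Ribosome biogenesis genes, which build and process ribosomal RNA, were lower as a group: 32 of 35 measured members had a negative log2 fold change, with a median of -0.30 (camera adjusted p = 2.8e-09; adjusted p = 0.24 with an estimated correlation). NIP7 (3.40-fold) and PNO1 (2.42-fold) fell and none rose, and 8 fell when adjusted over the list alone. FOXO target genes were higher as a group, with a median of 0.47 over 25 measured members (camera adjusted p = 0.00438; adjusted p = 0.24 with an estimated correlation), and adjusted over the list alone 11 rose and 4 fell. KLHL24 rose 2.44-fold, FBXO32, a ubiquitin ligase of muscle atrophy, rose 2.06-fold (log2 fold change of 0.99 by a dimmer probe; another, not above background in the controls, was at least 1.21-fold higher and did not pass), and SESN1, GADD45A and CDKN1B rose, while BCL6 itself and TSC22D3 (1.92-fold, with a second probe at -0.66 that did not pass) fell. No lysosome gene passed among 23 measured (median 0.12, camera adjusted p = 0.378).

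Most calls of at least 2-fold were falls, 197 against 47 rises (80.7%), whereas features at an unadjusted p under 0.05 split into 1582 lower and 1538 higher. Without background correction 84.9% of such calls were falls (157 against 28) and after median centring 86.9% were (226 against 34), which argues against background correction and quantile normalization as the whole cause. Unintended silencing by the siRNA, through partial matches in other transcripts, may contribute. It cannot be told apart from an effect of BCL6 depletion, because neither the siRNA nor the 3' UTR sequences were used here. Of the 12 largest falls, 4 belong to a fixed list and the other 8 to none, which does not bear on such matches. An effect of losing BCL6 also stays open. The 18 genes known from B cells, of which 2 rose and 2 fell, cannot test it for the falls. BCL6 represses those genes, so its loss would predict rises.

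The ERK output genes were lower as a group, with 8 of 22 measured members falling (camera adjusted p = 9.0e-10; adjusted p = 0.561 with an estimated correlation). Without DUSP6, the most changed member, their mean was -0.60 against -0.70 with it, and 7 of the other 21 measured members fell. Camera then gave an adjusted p of 2.8e-09, and 0.149 with an estimated correlation. The 0.149 and the 0.561 were adjusted over different sets of lists, and the unadjusted camera p were 0.0213 and 0.0256. Without background correction the whole list had a median of -0.44. These values argue against DUSP6 alone and against background correction as the whole cause. The lower levels of AXL and FGF2 may go with weaker input into ERK, which was not tested, since protein activity was not measured. HBEGF, another possible input, is itself on the ERK list, so its fall is part of the pattern. Neither receptor list passed as a group (camera adjusted p = 0.0914 for the ErbB list and 0.66 for the other receptor tyrosine kinases and ligands). Unintended silencing of a pathway member stays open for the same reason as above.

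The hypoxia and glycolysis genes had a mean log2 fold change of -0.45 (-0.49 between the arrays numbered 1 and -0.41 between those numbered 2). A difference in culture conditions between the groups, such as density or oxygen, stays open. Replicate 2 differed from replicate 1 by -0.25 over the same genes, so the list also moved between arrays of the same group. Each group holds both replicate numbers, so that shift cancels in the group difference. It therefore does not decide whether culture conditions differed between the groups. The estimated correlation between members was 0.362. A lower MYC level is a candidate explanation for part of the list's fall that was not tested on its genes. The ribosome biogenesis genes, which MYC activates, had a median of -0.30 (camera adjusted p = 0.24 with an estimated correlation, 2.8e-09 with the preset one). That test does not bear on the glycolysis genes themselves. Enzymes of the glycolytic chain other than ENO2 lay between -0.33 (PGK1) and 0.20 (HK2) and none passed. They held little of the list's fall, so a lower MYC level acting on them would explain little of it.

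MYLIP and CH25H rose, which prompted the hypothesis of higher activity of the sterol receptor LXR, for which MYLIP is a target. The other 13 measured LXR targets had a median of 0.0022, with 7 above 0 (camera adjusted p = 0.9). A median near 0 over members that went both ways does not decide, although the test set beforehand would have counted it against LXR. ABCA1 and ABCG1, transporters that LXR induces, had log2 fold changes of -0.07 (SE 0.16) and 0.0022 (SE 0.19), and ELOVL5 fell 2.75-fold. SESN1 and KLHL24 rose, and the hypothesis of higher FOXO activity was tested on the 22 other measured targets. They had a median of 0.41 (camera adjusted p = 0.00678, 0.24 with an estimated correlation, and 0.055 by fry). The 22 include GADD45A and CDKN1B, whose rises had been seen before the list was chosen, so these are not independent support. GADD45A is also on the p53 list, so the test does not tell FOXO from p53. The values go with the hypothesis by the test with the preset correlation alone, and FOXO activity was not measured.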
